A study of Homo sapiens with 2 samples.

How the data were processed

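Chromatin immunoprecipitation with an antibody to the FLAG tag, followed by sequencing (ChIP-seq), was carried out on 2 libraries of MCF7, a luminal, estrogen receptor-positive human breast cancer cell line. Per the labels, 1 library came from MCF7 cells that overexpressed FLAG-tagged TWIST1 (MCF7-TWIST1) and 1 from control MCF7 cells (MCF7-Ctrl). The groups were taken from the sample titles. With 1 library per group there was no replicate, so no test between groups and no p-value was computed. Intervals are of counting error or, for the median peak length on chromosome X, of resampled peaks. None measures variation between libraries.

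The table used was the authors' deposited peak list for MCF7-TWIST1 cells, with chromosome, start, end, length in bp and associated gene symbols for 18904 peaks. The submitters' processing notes name Trim Galore, Bowtie2 and MACS2 and the genome build hg38. Their versions, the peak threshold, the use of the control library in peak calling and the rule that assigned genes are not given in the sources used here. The deposited list, per the file headers, gives no fold enrichment, height, score or q-value per peak, and no read totals, so the sequencing depth is unknown and peak length was the one property of a peak that could be ranked. A peak list or reads of the control library were not analysed here, so the level of each peak in MCF7-Ctrl is not known from these data. Length equalled end minus start plus 1 in all 18904 rows, so coordinates are 1-based, and they are printed as deposited, on hg38.

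The gene symbols beside the peaks were tested before use against the positions of a RefSeq gene table of the same build (GRCh38.p14). Of 8404 symbols in the column, repeated ones included, 8236 matched a gene, 324 of them through an older symbol, 155 did not match and 13 were dates written by a spreadsheet in place of symbols. In 8899 consecutive rows nearly all symbols belonged to peaks 1051 rows further down, as described in the results. Genes were therefore assigned to peaks from coordinates alone. The search for a displaced run of rows was tested on 2 simulated tables and recovered the offset in 2 of 2.

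Peaks on the 24 chromosomes (18558) entered the comparisons, and 346 on other sequences were left out. A peak was counted at a gene end when its midpoint lay within 1 kb of either end of an annotated gene. The gene table held no strand, exons or genome sequence. Either end of a gene thus stood in for its transcription start site, exons, introns and untranslated regions were not told apart, and the planned measurements of E-box sequences (CANNTG, the sequence that basic helix-loop-helix factors bind), of the spacing between E-boxes and of other motifs were not made. Expected shares came from 1000 random placements of the same peaks within the span of genes on their own chromosomes. Expected shares in the bins of distance to a gene end came from 100 of these placements. Gaps in the assembly were not known and not excluded. Shares are given with Wilson 95% intervals and counts per Mb or per gene with exact Poisson 95% intervals. Chromosome length was taken as the position of the last gene end.

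A gene was counted as having a peak when the midpoint of a peak lay in its body or the 5 kb to either side. Without strand, the planned 5 kb upstream could not be told from downstream. For each of 13 gene lists, written before the data were examined, the number of genes with a peak was set against 10000 random lists of the same size, drawn from 38336 protein-coding and lncRNA genes and matched on gene length in 20 bins. A list stood apart when its percentile lay outside the central 95% of random lists, and a stricter limit was set for the 13 lists together by the Bonferroni rule. The procedure was tested on peaks placed at random: of 200 lists of 24 genes, 4% fell outside the central 95%, and after a peak was added to about 50% of the genes of each list, 99% did. These 200 lists came from the same genes as the random lists. The test thus could not show how lncRNA genes in the random lists affect lists of protein-coding genes. Percentiles describe the peaks of this library and are not a test of the condition.

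Genes named in the text were chosen by a rule written before the data were examined: the 10 peaks ranked highest on numbered chromosomes and X, up to 4 genes with the highest-ranked peak in each list, 12 genes named whatever their value, and the 5 genes with most peaks. The rule ranked peaks by fold enrichment or score; length took its place. Genes named outside the rule are marked as chosen after their values were seen.

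The alternatives tried were the longer 50% of the peaks, merging peaks and leaving out chromosome Y, other windows around gene ends, protein-coding genes only, overlap of the whole peak, wider or narrower gene regions, random lists matched on arms gained in MCF7 (1q, 17q and 20q) and peaks at least 10 kb from any other. Leaving out gene-free stretches, matching lists on gene density, using the deposited symbols for the lists and all alternatives for the share of peaks by gene part were added after the data had been seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.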

Results

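The data collected were FLAG ChIP-seq profiles of MCF7 cells with and without overexpressed FLAG-TWIST1, made to find the genomic regions that TWIST1 is associated with. TWIST1 is a basic helix-loop-helix (bHLH) transcription factor known for its part in the epithelial-mesenchymal transition (EMT). The deposited peak list of the MCF7-TWIST1 library held 18904 peaks with a median length of 306 bp (interquartile range 236 to 422 bp, full range 194 to 2533 bp). They covered 6.68 Mb, no pair overlapped, and the median gap between neighbours was 45.2 kb. There was 1 library per group and no peak list of MCF7-Ctrl was used, so all values below describe where the peaks of this 1 library lay and not a change from control cells.

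Where the peaks lay relative to genes was the first question. Peaks gathered at the ends of genes. Of 18558 peaks on chromosomes, 7633 (41.1%, Wilson 95% interval 40.4 to 41.8) had their midpoint within 1 kb of a gene end, against 6.88% of randomly placed peaks (range 6.37 to 7.48 over 1000 placements), a ratio of 5.98. For the ends of protein-coding genes the share was 33.5% against 2.90%, a ratio of 11.5. A further 6900 peaks (37.2%) lay inside a gene more than 1 kb from its ends, where random placement gave 52.3%. Peaks over 5 kb away from any gene made up 16.4% (3044 peaks) against 34.2% at random. In bins of distance, set against 100 of the placements, the excess was closest to the end itself. Under 100 bp from it lay 14.3% of peaks against 0.824% at random. Between 1 and 3 kb the shares were 10.5% and 10.3%.

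**Figure D1:**
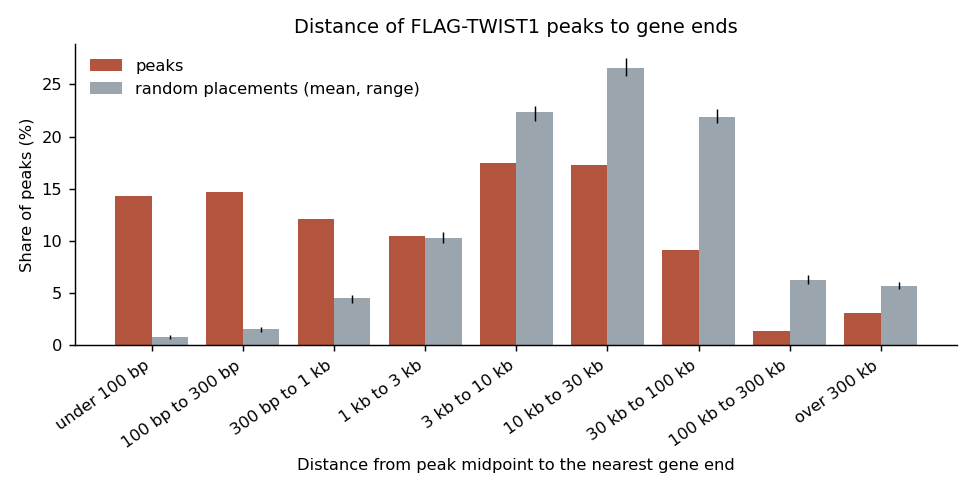
Share of peaks (%, y axis) by distance from the peak midpoint to the nearest gene end (x axis), for the 18558 FLAG-TWIST1 peaks on chromosomes and for random placements (mean, with lines from the lowest to the highest of 100 placements). Under 1 kb the peaks lie above each of these placements, with 14.3% under 100 bp against 0.824%, and from 3 kb on they lie below.

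The kinds of gene differed in how often a peak lay within 1 kb of either end. This was so for 33.5% of 20033 protein-coding genes (6711 genes), 12.3% of lncRNA genes and 6.64% of microRNA genes, each above all random placements. The lncRNA and microRNA genes that lie near protein-coding gene ends were not left out, so these shares may reflect peaks at those ends. Among 443 tRNA genes, 84 had a peak within 1 kb of an end, 12.7 times the share in random placements (mean 1.49%). Of the 250 tRNA genes without a protein-coding or lncRNA gene end within 5 kb, 37 had one (14.8%, Wilson 95% interval 10.9 to 19.7). The interval treats these genes as separate. Neighbouring tRNA genes can share a peak, and the different peaks were not counted. Small nucleolar RNA genes (2.59%) lay within the range of the placements (up to 3.17%). Pseudogenes had fewer than random placement gave (1.13% against 1.74%).

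Genes of cell identity and EMT were the next comparison, since TWIST1 is a regulator of EMT and MCF7 is a luminal, epithelial line. Over all protein-coding and lncRNA genes 37.4% had a peak, with 50.4% of the protein-coding and 23.2% of the lncRNA genes. Mesenchymal, luminal and basal genes had one more often than length-matched random genes of both kinds. These 3 calls were lost with random lists of protein-coding genes only, and differences between the lists were not tested. In the mesenchymal and EMT list, 23 of 33 genes had a peak in the gene body or within 5 kb, where random lists of the same gene lengths gave 14.3 on average (percentile 99.9). They included THY1, a surface glycoprotein (peak of 819 bp at 11:119417443–119418261), TWIST2, the close relative of TWIST1 (3 peaks, the longest at 2:238864093–238864785), COL1A1, a type I collagen chain, and AXL, a receptor tyrosine kinase, with 3 peaks. VIM, which codes for the intermediate filament vimentin, had a peak 0.281 kb from a gene end (10:17228276–17228769), and SNAI2, a zinc-finger repressor active in EMT, had one 0.171 kb from an end (8:48921368–48921832). No peak was listed for CDH2 (N-cadherin), ZEB1 or PDGFRA by the same criterion.

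Of the 30 luminal and estrogen receptor genes, 19 had a peak against 12.3 at random (percentile 99.4). These included CCND1 (cyclin D1) and ERBB3 with 3 peaks each, ERBB2 with 2, and ELF3. ESR1, the estrogen receptor alpha gene, had 2 peaks inside the gene, at 6:151764286–151764642 and 6:152095265–152095626, 108 and 34.2 kb from its nearest end. This was no more than the 2.52 expected from its length, with 5 kb to either side, and the density of peaks on its chromosome. GATA3, a luminal transcription factor, had 1 peak 1.15 kb from an end (10:8073827–8074270), where 0.308 were expected in the same way. The estrogen-responsive gene GREB1 had 1 inside the gene (2:11498631–11498933), close to the 0.972 expected. FOXA1 and TFF1 had none within 5 kb, and their nearest peaks lay 42.6 and 130 kb away. Of the basal and myoepithelial genes, 16 of 24 had a peak against 9.78 (percentile 99.6), among them CRYAB, the adhesion receptor CD44, MYLK and CAV1 (caveolin-1). Of the epithelial junction and polarity genes, 18 of 32 had a peak against 14.0, within the central 95% of random lists (percentile 92.5), among them PKP3 (plakophilin 3), CRB3, PARD6B and ST14. CDH1, which codes for E-cadherin, had a single peak of 240 bp inside the gene (16:68792947–68793186), 42.5 kb from its nearest end. From its length and chromosome 0.715 peaks were expected. With random lists of protein-coding genes only, the mesenchymal (percentile 97.2), luminal (90.4) and basal (93.5) lists came within the central 95% as well. With 50 kb to both sides of the gene the mesenchymal (75.8) and luminal (77.5) lists were within it and the epithelial list above (98.0). In the longer 50% of the peaks the mesenchymal (96.5), luminal (89.9) and basal (95.5) lists were within it.

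Genes described elsewhere as TWIST1 targets had a peak in 9 of 17 cases against 6.81 at random (percentile 86.1), which did not stand apart. CDKN1A, which codes for the cell cycle inhibitor p21, had the longest peak among these genes (1134 bp, 6:36678426–36679559), followed by HMGA2, SNAI2 and ESR1. The TWIST1 gene itself had no peak in the gene or within 50 kb, and the nearest lay 591 kb away (7:19708824–19709085).

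Genes of the bHLH family and its partners had peaks more often than length-matched random genes. Of 24, 20 had a peak against 8.68 at random (percentile 100). BHLHE40 had 3 peaks, with a longest of 897 bp (3:4978423–4979319), and TFAP4 had 3. ARNT and BHLHE41 had 1 each. The 4 genes without one were TWIST1 and, named here after their values were seen, HAND2, TCF12 and TCF4. Of the cytoskeleton, adhesion and migration genes, 23 of 26 had a peak against 12.9 (percentile 99.995). ARHGEF2, an exchange factor for RhoA, had a peak of 1032 bp (1:155961983–155963014), ACTN4 (actinin alpha 4) had 7 peaks, FSCN1 (fascin) 2 and TPM1 (tropomyosin 1) 1. Among immediate early and AP-1 genes, 15 of 20 had a peak against 5.97 (percentile 100), with EGR1 (1019 bp, 5:138464245–138465263), FOSL2 (4 peaks), ATF3 and DUSP1 (3 peaks) the longest. These 3 lists stayed above the central 95% with protein-coding genes only.

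Among signalling and growth genes, 19 of 24 TGF-beta and BMP genes had a peak against 12.3 (percentile 99.755), including LTBP1 (5 peaks), the receptors TGFBR2 (4 peaks) and TGFBR1, and SMAD3 (7 peaks). Of the WNT and Notch genes, 15 of 24 had a peak against 11.4, which did not stand apart (percentile 93.2). RBPJ, the DNA-binding effector of Notch, had a peak of 1021 bp (4:26318829–26319849), and the Notch ligand JAG1, LRP5 and APC had 2, 3 and 2 peaks. Of the cell cycle and DNA replication genes, 17 of 26 had a peak against 9.73 (percentile 99.76), among them PCNA and RRM2 (3 peaks each), CDK4 and MCM2. The TGF-beta and cell cycle lists fell to percentiles of 97.4 and 94.4 with protein-coding genes only. The TGF-beta list was also within the central 95% in the longer 50% of the peaks (94.2), with 50 kb to both sides (95.8) and with 5 kb around either gene end (93.9).

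The 2 comparison lists were each set against random lists and not against each other. Of 22 measured housekeeping and highly transcribed genes, which often give nonspecific signal in ChIP, 19 had a peak against 6.38 at random (percentile 100), the highest ratio of the 13 lists at 2.98. RPLP0, HSP90AB1, PKM and EEF1A1 had the longest peaks among them. In the longer 50% of the peaks the housekeeping ratio was 2.82, below the 3.58 of the immediate early list. Of 24 genes of blood, liver and nerve cells, 8 had a peak against 9.74 (percentile 23.8), with MBP, GRIN1, CD3E and SPI1 the longest. The mesenchymal, bHLH, cytoskeleton, immediate early and housekeeping lists, 5 of the 13, passed the stricter limit. Against random lists of protein-coding genes only, the mesenchymal list did not stand apart (percentile 97.2), and the other 4 still passed the stricter limit. Of all 38336 protein-coding and lncRNA genes, 14353 (37.4%) had a peak, and of the protein-coding genes alone 50.4% did.

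**Figure D2:**
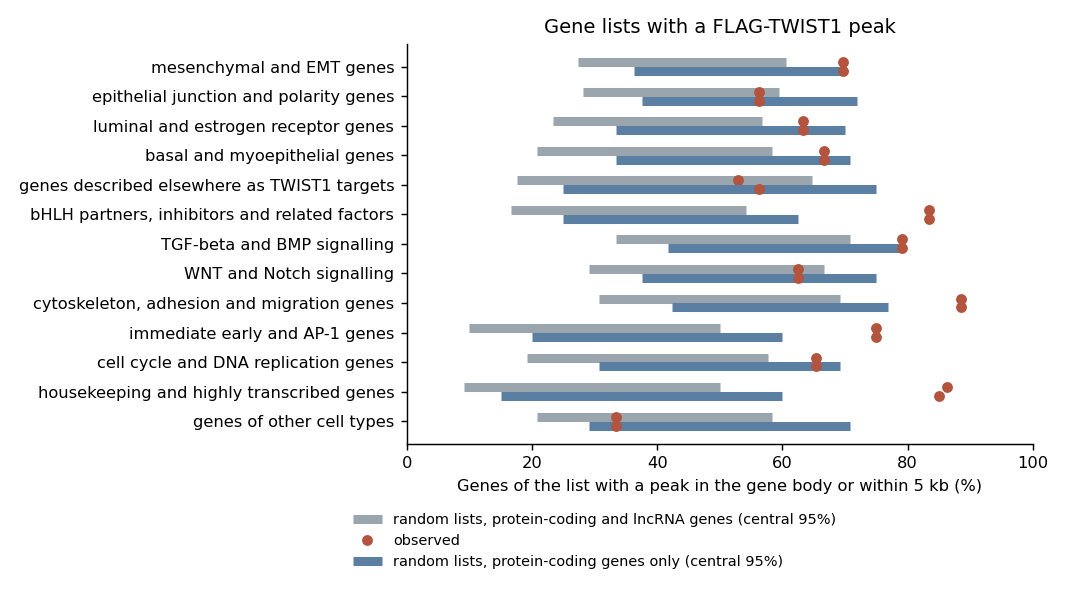
Share of the genes of each list with a peak in the gene body or within 5 kb (%, x axis) for the 13 lists (y axis). Points are observed shares and thick lines the central 95% of 10000 length-matched random lists, drawn from protein-coding and lncRNA genes (grey) or protein-coding genes only (blue). The points of 9 lists lie above the grey lines, and those of the bHLH, cytoskeleton, immediate early and housekeeping lists also lie above the blue ones.

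The genes with most peaks were long genes with peaks inside them, and each is set against the number expected from its length and the density of peaks on its chromosome. HIVEP3 on chromosome 1 had 21 peaks in 530 kb (4.27 times the expected number), FRMD4A on chromosome 10 had 18 in 687 kb (3.34 times) and NTM on chromosome 11 had 17 in 966 kb (2.19 times). SEPTIN9 on chromosome 17 had 17 in 219 kb (5.10 times). PVT1, a lncRNA gene next to MYC on chromosome 8, had 17 in 307 kb (9.87 times). Of these genes, HIVEP3 had 2 and PVT1 1 of its peaks within 1 kb of an end.

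Peaks were spread unevenly over chromosomes. Chromosomes 19 and 17 had the highest densities, with 19.1 (exact Poisson 95% interval 18.0 to 20.2) and 14.5 (13.7 to 15.4) peaks per Mb, which were 3.17 and 2.42 times the number expected from their length. Counted per protein-coding gene, chromosome 19 had 0.771 peaks and chromosome 17 had 1.04, inside the range of the numbered chromosomes, from 0.698 on chromosome 16 to 1.41 on chromosome 10. Chromosome X had 121 peaks, 0.776 per Mb (0.643 to 0.927) and 0.143 per protein-coding gene (0.118 to 0.170), below every numbered chromosome on both scales. The arms 1q and 17q, which are gained in MCF7, had 0.987 and 0.992 peaks per protein-coding gene against 1.04 and 1.06 on 1p and 17p, with overlapping intervals. On 20q the value was 1.16 (1.05 to 1.27) against 1.02 (0.875 to 1.18) on 20p, also with overlapping intervals. Per Mb, 20q had 11.6 peaks (10.5 to 12.7) against 6.99 (6.02 to 8.08) on 20p, with intervals apart. The intervals per Mb of 1q and 17q overlapped those of 1p and 17p.

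**Figure D3:**
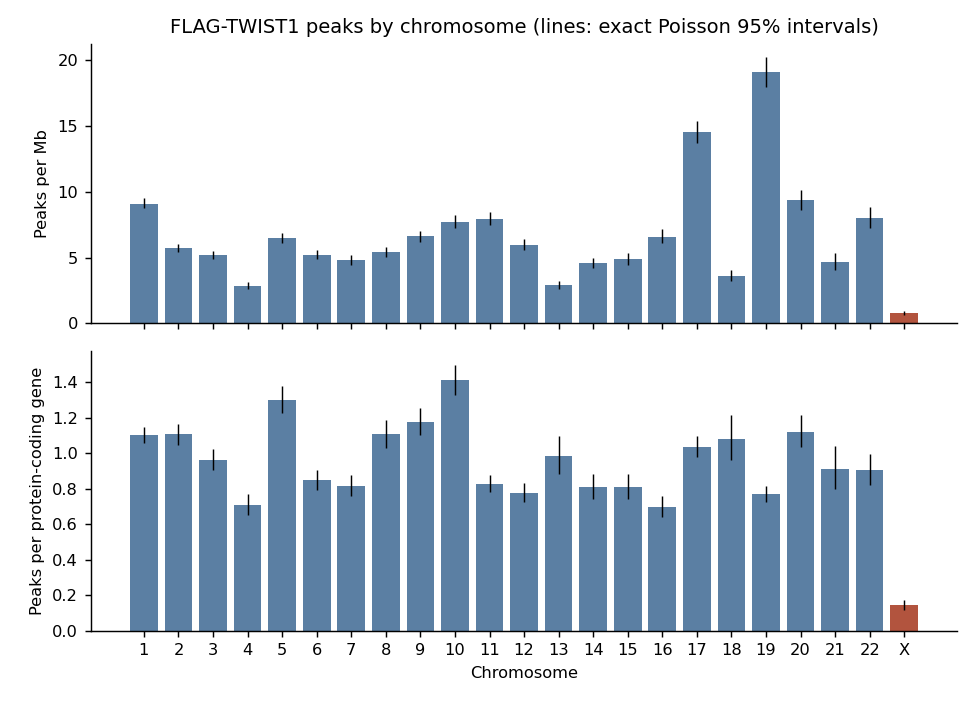
Peaks per Mb (upper panel) and per protein-coding gene (lower panel) for each numbered chromosome and X (x axis). Bars are the values of the 1 MCF7-TWIST1 library and thin lines exact Poisson 95% intervals. Chromosomes 17 and 19 are highest per Mb, and X is lowest in both panels with 0.776 per Mb and 0.143 per gene.

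A part of the list lay far from any gene. The 29 gene-free stretches of 2 Mb or more held 661 peaks (3.56%) on 6.67% of the chromosomes' length, which is 3.21 per Mb against 6.01 over all chromosomes. They were uneven. Of the 29, 24 lay below that average and 7 held no peak, while 519 of the peaks lay in the 4 fullest, on chromosomes 1, 5, 10 and 19. The stretches on chromosomes 19 (24179012–27681071) and 5 (45696381–50396191) had 42.0 and 30.9 peaks per Mb. Gaps in the assembly, where no read can map, and repeated sequence were not analysed. Neither the empty nor the full stretches can therefore be read as a property of binding. Peaks in gene-free stretches were shorter in the median, at 261 bp against 308 bp outside. Of the 10 longest peaks, however, 6 lay in gene-free stretches, among them the longest (2533 bp, 16:46398592–46401124, 179 kb from the nearest protein-coding gene, SHCBP1) and the next (1939 bp, 5:49658352–49660290, 737 kb from EMB). Of the 10, 2 lay inside a gene, namely a peak in KCNIP3 (2:95315460–95317273) and one in LOC124902042 (8:144901403–144902973), 0.011 kb from an end of ZNF250.

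The gene symbols in the deposited table did not stand beside their peaks throughout. From row 8948 to row 17846 (8899 rows, 47.1% of the table), 1 of 3717 matched symbols named a gene that the peak in its row lay in or within 10 kb of. This was ESR1, beside the peak at 6:152095265–152095626. For 3700 (99.5%) the peak 1051 rows further down lay in the gene or within 10 kb. Outside this run the peak in the same row did so for 4499 of 4518 symbols (99.6%), leaving out 1 symbol beside a peak that was not on a chromosome. The symbol SNAI2 stood beside a peak at the start of chromosome 7 and its own peak on chromosome 8 was 1051 rows below. Cells without a symbol before the run leave its first row uncertain by 21 rows. The symbols of the last 1051 peaks were repeated, since the 362 cells with symbols beside them also stood 1051 rows above. A further 1051 peaks, from 19:10424157 to 2:15170146, had no symbols of their own anywhere in the column. For 496 genes, one of these peaks without symbols lay within 1 kb of an end, 409 of them protein-coding, including ACTN4, AKT2, AXL, JUNB, JUND, TGFB1 and USF2 of the lists (AKT2, JUNB, JUND, TGFB1 and USF2 are named here after their values were seen).

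**Figure D4:**
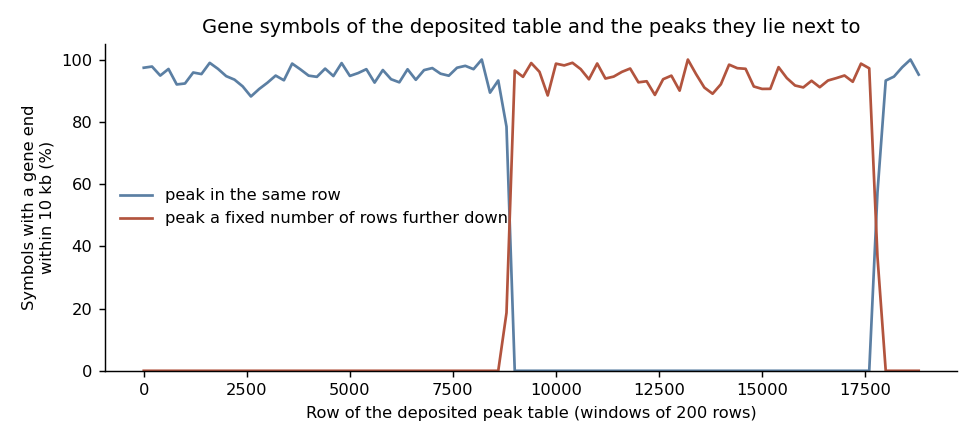
Share of gene symbols with a gene end within 10 kb of a peak (%, y axis) along the rows of the deposited table, in windows of 200 rows (x axis). Blue is the peak in the same row and red the peak 1051 rows further down. The red line replaces the blue one between rows 8948 and 17846.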

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

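Of the tests in this part, those of gene density and of a missing part of chromosome X were written before their results were seen, and the others after. With no peak list of the control library and 1 library per group, no biological explanation was tested.

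Values in parts of the table that the comparisons do not use were looked at because they lie above the 3 counts that a count of 0 allows. There were 206 peaks on alternate sequences of the assembly, 135 on unplaced or unlocalised sequences and 5 on the mitochondrial genome. The column of gene symbols, not used for assignment, had 8899 rows out of register with their peaks.

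The displaced gene symbols form 1 run of rows. A shift between genome builds is argued against, because 93.9% of the symbols in the run belong to another chromosome than the peak they stand beside. A candidate explanation is that the cells of this column were copied or moved up by a fixed number of rows, since 94.6% of the symbols have a gene end within 10 kb of the peak 1051 rows further down. A move that left the last rows empty is argued against, because 100% of the 362 cells with symbols in the last 1051 rows also stand 1051 rows above. Whether cells were copied, or moved and the last rows filled in again, stays open.

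Most gene lists held more genes with a peak than length-matched random lists, housekeeping genes included. lncRNA genes, which have fewer peaks and dilute random lists, are not the whole cause, since 4 lists stayed above the stricter limit with protein-coding genes only, although 5 of the 9 lists came within the central 95%, and with gene density matched as well 3 did. Random genes were also matched on local gene density, as 3 classes of the number of gene ends within 100 kb. Of these 4 lists, 4 stayed above (lowest percentile 99.95), so differences in density between the classes are argued against for them. Density within a class was not matched and stays open. Whether peaks lie at active genes whatever their role stays open, because gene activity was not measured and the list of other cell types, at percentile 4.58 among protein-coding genes, lay within the central 95%. Binding of TWIST1 at these genes stays open and was not tested, because no control peaks, expression values or sequence were analysed here.

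Chromosome X had few peaks. It had 848 protein-coding genes, more than the 769 of chromosome 4, which had 546 peaks. A low number of genes is argued against, because X had 0.143 peaks per protein-coding gene (upper limit 0.170) against 0.698 on the lowest numbered chromosome. A missing or unmappable part is argued against too, as 0 of 15 bins of 10 Mb reached that value and the highest had 0.310. Fewer reads from X, as fewer copies would give, may contribute: the median peak length on X was 257 bp (bootstrap 95% interval 242 to 274) against 288 to 323 bp on numbered chromosomes. Weaker binding on X would also give shorter peaks, and read depth on X was not analysed here, so both stay open.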

How the results depend on the processing

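The alternatives that leave out gene-free stretches, match on gene density or use the deposited symbols for the lists, and all those for the share over 5 kb outside genes, were chosen after seeing the data. The q-value threshold and all E-box, spacing and motif alternatives were not run, because the peak list held no q-value and no genome sequence was used. Ranking by length took the place of fold enrichment. The unknown depth limits every count, since a list from deeper sequencing would hold other numbers of peaks. Where values moved, the cause was not tested unless given.

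The median peak length was 422 bp in the longer 50% of peaks, by construction. The share of peaks within 1 kb of a gene end was 46.5% in the longer 50% and 42.6% without gene-free stretches. It was 34.1% for a window of 500 bp and 51.6% for 3 kb, 33.5% for protein-coding genes, and 42.4% for any overlap of the peak. In the rows before the displaced run, 39.6% of peaks had a deposited symbol. That is another measure, since the rule that assigned symbols is not known. The ratio to random placement was 5.82 without gene-free stretches. The share over 5 kb outside genes was 14.4% in the longer 50% and 13.3% without gene-free stretches. Observed over expected peaks were 2.63 on chromosome 17 and 0.0810 on X in the longer 50%, 2.86 on chromosome 19 without gene-free stretches, and 2.06, 2.59 and 0.164 on chromosomes 17, 19 and X for peaks at least 10 kb from any other. No direction of a called result reversed in the alternatives run.

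Of 13 lists, 9 stood above random lists, and 4 did with protein-coding genes only. The bHLH, cytoskeleton, immediate early and housekeeping lists did so under each of the 7 alternatives that moved any list. Leaving out gene-free stretches, or merging peaks and leaving out Y, moved no list's percentile and so tests nothing here. The other calls changed as follows, as percentiles. In the longer 50% of peaks the mesenchymal list was at 96.5, luminal 89.9, basal 95.5 and TGF-beta 94.2, while WNT and Notch rose to 99.0. With 50 kb to both sides, mesenchymal was at 75.8, luminal 77.5 and TGF-beta 95.8, and epithelial rose to 98.0. With 5 kb around either gene end TGF-beta was at 93.9. With protein-coding genes only, mesenchymal was at 97.2, luminal 90.4, basal 93.5, TGF-beta 97.4 and cell cycle 94.4, since random lists then held more genes with a peak. With gene density matched as well, in 3 classes, 6 lists stood above, with mesenchymal (97.6) and TGF-beta (98.5) above again. Luminal was then at 93.9, basal 93.1 and cell cycle 95.6. By deposited symbols TGF-beta was at 97.4, and epithelial (99.6) and TWIST1 targets (97.9) rose above. The random lists here held lncRNA genes too. Some peaks had no symbols of their own in that column, among them a peak within 1 kb of an end of TGFB1, so these changes can come from the column.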

Other observations

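Gene families differed widely in how many members had a peak in the gene body or within 5 kb. Families were taken, after the data had been seen, as the 156 sets of 15 or more protein-coding genes whose symbols start with the same letters, and each was set against 10000 length-matched random lists of protein-coding genes, with limits corrected for 156 sets. KLF genes, which code for Krüppel-like zinc-finger factors, had a peak in 16 of 18 cases against 9.10 at random, and VPS genes, named for vacuolar protein sorting, in 30 of 35 against 19.4. Their genes, with 5 kb to either side, overlapped 25 and 43 different peaks. Below their random lists, olfactory receptor genes (OR) had a peak in 5 of 392 cases against 121, UGT genes, many of them glucuronosyltransferases, in 0 of 22 against 12.7, beta-defensins (DEFB) in 0 of 39 against 14.0, and CLEC genes of C-type lectins in 3 of 31 against 15.1. In all, 3 sets lay above and 13 below their limits. The limits, at percentiles 99.984 and 0.0160, rest on very few of the 10000 random lists. Calls close to them are therefore uncertain, that of KLF (99.99) among them. Random lists treat genes as separate, and whether the members of these sets lie together was not examined. The counts can thus rest on fewer places than genes. How well reads map to the genes of these sets was not analysed either, so the low counts cannot be read as a lack of binding.

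The 3 protocadherin gene sets differed in this count. All 22 PCDHG genes had a peak and 0 of 15 PCDHA genes did, against 13.8 and 9.54 at random, while PCDHB genes (2 of 16 against 5.64) lay within their limits. The PCDHG genes overlap each other, and the count of 22 rests on 1 peak that lies in all of them, so genes of such clusters are not separate observations.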
